A study of Mus musculus with 6 samples.

How the data were processed

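Bulk RNA sequencing was analysed in 6 libraries of RAW264.7, a mouse macrophage-like line that grows in culture. The labels put 3 libraries in a wild-type group with no shRNA recorded, called control here. The other 3 are labelled as treated with a lentiviral shRNA (short hairpin RNA) against ERMAP, an erythroid membrane-associated protein of the butyrophilin family. The treatment protocol text names the lentivirus for all 6 samples, controls included, while the treatment tag stands only on the labelled group, so whether the controls were transduced is not settled by the labels. No label describes a control lentivirus or a non-targeting shRNA. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

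The authors deposited whole-number read counts per gene for 54532 genes, with Ensembl identifiers, gene names, biotypes, gene lengths and coordinates. Reads were aligned with HISAT2 to mm10, per the submitters' processing notes. The program that counted the reads, its strand setting, the gene annotation release and all versions are not given in the sources used here. The authors also deposited FPKM values per library, and a mean FPKM per group. A check of the file showed that FPKM equals the count divided by gene length and by 1 constant per library, and that this constant lies within -0.15% to 1.20% of the library's summed count. The deposited group means equal the means of the FPKM columns. Of the gene identifiers, 54409 also occur in the GENCODE vM21 annotation, and 98.3% of those have the same chromosome, start, end and strand there. GC content was taken from vM21 transcripts. Column names of the tables show the group of each library and a number, and the numbers used here are those. They could not be tied to single samples, because every sample title of a group begins with the same name.

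Counts were tested with the quasi-likelihood method of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM factors, the filterByExpr filter at its minimum count of 10, robust dispersion and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. TMM-scaled CPM (counts relative to library size) are given as mean ± SD over 3 libraries, fold changes are log2 values of libraries labelled ERMAP shRNA over control, and 95% intervals come from the same model. A gene with no control count is given as a lower bound, against a floor of 3 counts over the control group. A gene with 1 to 3 control counts is given as a ratio of summed counts with an exact binomial interval. Intervals and floors of this kind cover counting error only.

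Before the data were examined, 26 gene lists, 8 lists of markers of other cell types, the tests, most alternatives and the rule for named genes were fixed. The rule takes Ermap, then the 8 protein-coding genes with the largest rise and the 8 with the largest fall among called genes with a mean CPM of at least 5 in the higher group and no overlap between groups. It adds up to 3 called members of each list with a mean CPM of at least 1, or the most abundant member where none was called, and lets the text leave out members of lists that were not called. It names 47 genes, of which 15 are left out here on that ground. Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, which asks whether a list moves one way without comparing it with other genes, were alternatives.

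The edgeR test and camera were tested on simulated data, with levels and dispersions taken from a fit to these counts. No other method was tested in this way. Counts were drawn a single time for 12333 genes of this comparison. In them 200 genes were changed up or down, and a list of 30 more genes was raised 1.5-fold. Of the 200, the test recovered 25.4% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 92.4% of those changed 4-fold. False calls made up 9.09% of its calls, above the nominal 5%. Of 25 unchanged lists, 0 were called, and the raised list was called. Genes were drawn independently there, so this does not cover lists whose members are correlated. In the fixed lists the estimated correlation reached 0.506 (immediate early genes).

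Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, other filters on low counts, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, a replicate block, and leaving out each library. A fit with library weights and a fit with offsets for GC content per library were added after the data had been seen. Reactome pathways from fgsea 1.28.0, with 10 to 300 tested genes, were also tested after the data had been seen. Summed counts per library ranged from 13447021 to 16602734. No pair of libraries of a group agreed within sampling noise: over genes with at least 20 counts in a pair, chi-square per degree of freedom ranged from 3.35 to 67.2. No row lacked a gene name, and no library column was left out.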

Results

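RNA was measured in 6 libraries of RAW264.7 mouse macrophages: 3 control libraries and 3 libraries labelled ERMAP shRNA. The series' design text gives the question as which genes differ once ERMAP is knocked down. Summed counts per library ranged from 13447021 to 16602734, and 12491 genes passed the filter on low counts.

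Ermap, the gene the shRNA is said to target, was not lower in the libraries labelled ERMAP shRNA. Ermap (ENSMUSG00000028644) lies on the minus strand of chromosome 4 in mm10, from 119175457 to 119190011, and is a protein-coding gene. It had 12, 12 and 3 counts in the control libraries and 10, 21 and 14 counts in the libraries labelled ERMAP shRNA. Mean levels were 0.584 ± 0.338 CPM (SD, n = 3) in control and 1.03 ± 0.335 CPM (SD, n = 3) in the labelled group, and mean deposited FPKM was 0.109 and 0.193. The log2 fold change was 0.81 (SE 0.52, 95% interval -0.38 to 2.01, edgeR adjusted p = 0.929), in the direction opposite to the label. With edgeR, changes within that interval could not be excluded at these counts. It is not a limit of detection, since a fall below its lower bound could also have gone uncalled. Limma-trend on log2(FPKM + 1) gave 0.11. The fit with library weights, added after the data were seen, called Ermap higher (1.66, adjusted p = 0.0382). That fit leaned on control replicate 3, with 3 Ermap counts, at a weight of 3.26, against 0.772 and 0.0903 for control replicates 2 and 1. Leaving out 1 library gave edgeR values from 0.41 (without control replicate 3) to 1.12 (without control replicate 1). Every direction below is that of the libraries labelled ERMAP shRNA against control, and no decrease of Ermap mRNA was seen behind the label.

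Interferon-stimulated genes, which cells switch on in response to interferons, made up many of the changes. In the libraries labelled ERMAP shRNA, 126 genes rose and 17 fell (edgeR, adjusted p under 0.05, n = 3 per group), and 34 of the genes that rose belong to the interferon list fixed beforehand. Cmpk2 rose from 0.787 ± 0.161 to 35.0 ± 2.24 CPM, Rtp4 from 1.77 ± 0.141 to 62.0 ± 3.61 CPM and Ifi44 from 3.99 ± 1.18 to 184.1 ± 10.4 CPM (mean ± SD, n = 3). Tgm2, a transglutaminase, fell from 6.50 ± 1.33 to 0.621 ± 0.366 CPM, and Acp5, the tartrate-resistant acid phosphatase of osteoclasts, from 9.21 ± 1.78 to 1.91 ± 0.160 CPM. The groups did not overlap in CPM in any of the 143 called genes. Among all tested genes 14.2% did not overlap, where chance gives 10%. At an unadjusted p under 0.05, 464 genes were higher and 380 lower. The log2 fold change was at least 1 in 103 of the genes that rose and -1 or lower in 9 of those that fell.

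Control replicate 1 stood apart from the other libraries. Mitochondrial transcripts made up 3.69% of its counts (95% Wilson interval 3.68% to 3.70%), against 1.71% to 2.18% in the other 5 libraries. Its log2 deviation from the other controls fell with the GC content of transcripts (Spearman rho = -0.817 across 9373 protein-coding genes, which are not independent replicates). Without control replicate 1, 342 genes were called higher and 280 lower, including all 126 and 17 called with it. Leaving out any other single library gave 73 to 96 genes higher and 3 to 11 lower, with 73 without replicate 3 of the labelled group.

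**Figure D1:**
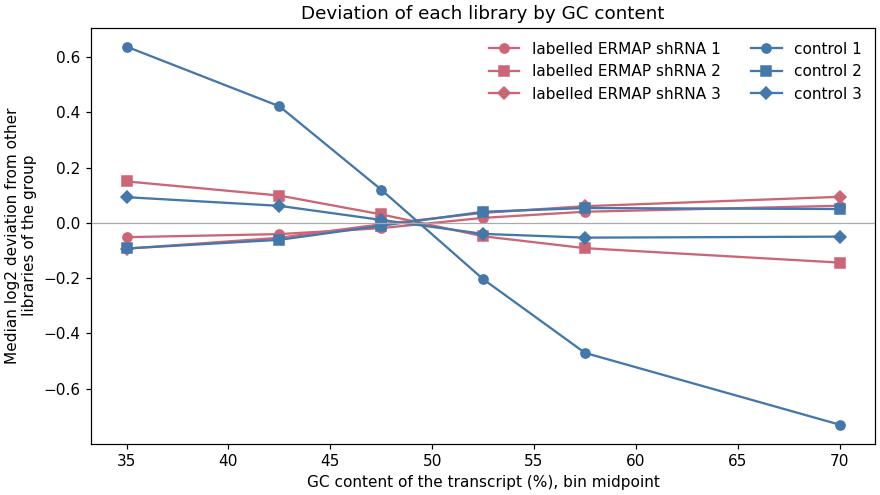
Median log2 deviation of each library from other libraries of its group (control replicate 1 is left out as a reference), by GC content of the transcript in percent, with 1 line per library. Control replicate 1 runs from 0.64 in the lowest GC bin to -0.73 in the highest, and the other libraries stay between -0.14 and 0.15.

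The 8 named genes with the largest rise were Apol9b, Ifi44l, Apol9a, Ddx60, Ifi44, Cmpk2, Rsad2 and Rtp4. Several are textbook targets of type I interferon: Rsad2 encodes the antiviral protein viperin and Cmpk2 a nucleotide kinase beside it. Apol9b had 2 counts in all control libraries and 900 in the labelled group, a ratio of 477 (95% interval 132 to 3943). The fitted log2 fold changes were 8.26 for Ifi44l (SE 0.27), 7.59 for Apol9a (SE 0.33), 5.63 for Ddx60 (SE 0.46) and 5.20 for Rsad2 (SE 0.48), with edgeR adjusted p from 4.99e-06 to 0.0014. Those of Ifi44, Cmpk2 and Rtp4 were 5.53 (SE 0.21), 5.47 (SE 0.18) and 5.12 (SE 0.14), with edgeR adjusted p from 4.33e-06 to 7.42e-06. Apol9a and Apol9b are near-identical copies, and how reads were split between them is unknown. All 8 stayed called whichever library was left out. Apol9a and Rsad2 rest on 9 and 6 control counts, and their log2 fold changes were 8.55 without control replicate 3 and 6.05 without control replicate 2.

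Of the 8 largest falls, log2 fold changes were -3.37 for Tgm2 (SE 0.39), -2.79 for Atp6v0d2 (SE 0.43), -2.26 for Acp5 (SE 0.22), -1.58 for Kirrel3 (SE 0.24), -1.53 for Slc6a4 (SE 0.21) and -1.47 for Aqp1 (SE 0.16). They were -0.92 for Adgre5 (SE 0.13) and -0.91 for Anpep (SE 0.12), with edgeR adjusted p of the 8 from 0.00168 to 0.0243. Atp6v0d2 encodes a subunit of the proton pump, Slc6a4 the serotonin transporter, Aqp1 a water channel and Anpep an aminopeptidase. Tgm2, Acp5 and Aqp1 stayed called whichever library was left out. Atp6v0d2 lost its call without each labelled replicate in turn (adjusted p up to 0.128), and Kirrel3 without each library other than control replicate 1 (up to 0.176). Slc6a4 lost it without control replicate 3 or labelled replicate 2 or 3 (up to 0.104), Adgre5 without control replicate 2 or 3 or labelled replicate 1 or 3 (up to 0.128), and Anpep without control replicate 3 or any labelled replicate (up to 0.0993).

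**Figure D2:**
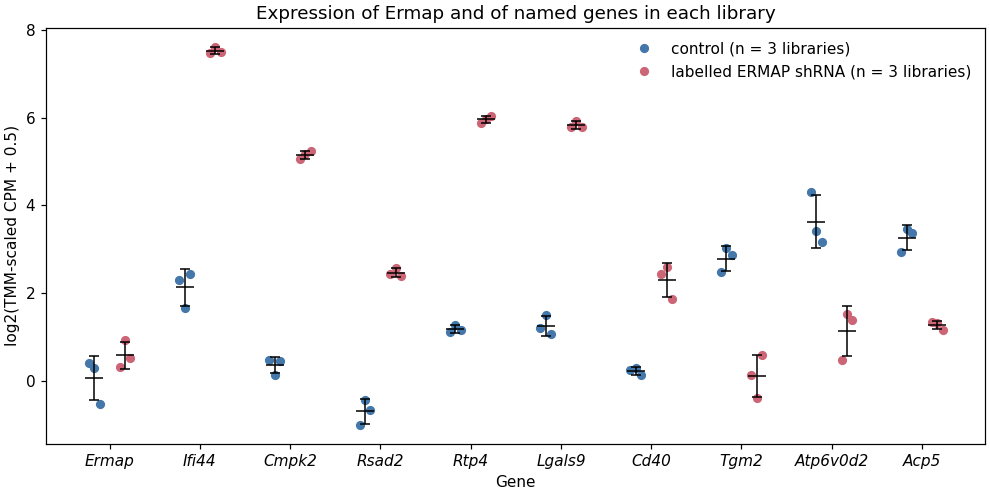
Expression of Ermap and of 9 named genes on the log2(CPM + 0.5) scale, each point a library, with the mean and SD of 3 libraries per group in black. Ermap overlaps between groups, and the other 9 genes do not.

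Interferon-stimulated genes were tested as a list of 42, of which 38 passed the filter. Of these, 34 rose, 0 fell and 4 did not pass the test, and all 38 passed when adjusted over the list alone. The median log2 fold change was 2.94, and stays 2.94 with Mx1 at its lower bound. Mx1, an antiviral GTPase, had 0 counts in control and 53 in the labelled group, at least 18.7-fold higher against a floor of 3 counts over the control group. It lost its call without any single library other than control replicate 1 (adjusted p up to 0.168). The list was called by camera, with adjusted p = 7.03e-05 with an estimated correlation. Without control replicate 1, 37 of 38 rose, and without any other single library 29 to 32 did. The copies among Oas1a and Oas1g, and relatives of Slfn5, Trim30a and Phf11d, can share reads and are uncertain singly.

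MHC class I presentation genes, which load and show peptides to T cells, moved up as a list by small amounts. Of 21 tested, 3 rose and 0 fell, 14 rose when adjusted over the list alone, all 21 had positive values, and the median log2 fold change was 0.56. H2-T23, a non-classical class I gene, rose from 29.8 ± 4.05 to 103.2 ± 10.2 CPM (mean ± SD, n = 3), Tap1, a peptide transporter, by a log2 value of 1.01 (SE 0.17) and Psme1, a proteasome activator, by 0.56 (SE 0.09). The list was called (camera adjusted p = 7.31e-17) and stayed called with an estimated correlation (adjusted p = 0.0412). H2-T23 has close relatives that can share its reads. Without control replicate 1, 13 of 21 rose, and without any other single library 1 or 2 did. Psme1 lost its call without each library other than control replicate 1 (adjusted p up to 0.219), and Tap1 without control replicate 3 or any labelled replicate (up to 0.216).

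A list of T cell co-signalling genes was called higher, and Lgals9, Cd40 and Icosl were its members that rose. It was fixed together with 8 other members of the butyrophilin family, to which ERMAP belongs, and 0 of those 8 passed the filter, with at most 2 counts each over the 6 libraries, so the result says nothing of that family. Of 15 genes tested, 3 rose and 0 fell, while 5 were higher and 2 lower when adjusted over the list alone. Lgals9, a galectin that binds receptors on T cells, rose from 1.91 ± 0.394 to 56.4 ± 3.44 CPM. Cd40, a co-stimulatory receptor, rose from 0.669 ± 0.067 to 4.55 ± 1.28 CPM, and Icosl, the ligand of ICOS, from 6.52 ± 1.10 to 13.8 ± 0.371 CPM (mean ± SD, n = 3). The median log2 fold change was 0.10, against 0.21 without control replicate 1, 0.06 without control replicate 3, 0.16 and 0.04 without labelled replicates 1 and 2, and 0.17 with GC offsets. Camera gave adjusted p = 1.87e-08, and adjusted p = 0.0399 with an estimated correlation. Icosl lost its call without any single library other than control replicate 1 (adjusted p up to 0.137). Without control replicate 1, 3 rose and 2 fell.

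Osteoclast genes, which macrophage-lineage cells express as they turn into bone-resorbing cells, were called lower as a list. Of 13 tested, 2 fell, Acp5 and Atp6v0d2, and 0 rose, while 5 fell when adjusted over the list alone. The median log2 fold change was -0.36, and -0.24 without control replicate 1. Nfatc1 and Ocstamp, picked after their values were seen, had log2 fold changes of -0.53 (adjusted p = 0.0527) and -0.99 (adjusted p = 0.0885). Camera gave adjusted p = 4.82e-06, and adjusted p = 0.0412 with an estimated correlation. Without control replicate 1, 5 of 13 fell and Car2 rose, and leaving out any one labelled replicate left Acp5 as the only member that fell. Atp6v0d2 also lost its call in limma-voom (adjusted p = 0.0548), with the replicate block (edgeR, 0.107) and in limma-trend on FPKM (0.0584 to 0.138). DESeq2 kept it (adjusted p = 1.22e-09).

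Few members of the inflammatory lists passed the test over all genes. Of 31 genes of the Toll-like receptor and NF-kB pathway, only Tlr3, a sensor of double-stranded RNA, rose (log2 fold change 1.45, SE 0.25, edgeR adjusted p = 0.045), while 4 rose when adjusted over the list alone. The median was 0.25, camera adjusted p = 0.000125, and adjusted p = 0.0444 with an estimated correlation. Of 9 cytokines and mediators, Tnf rose from 27.6 ± 1.35 to 42.1 ± 2.62 CPM and Acod1, which makes itaconate, from 1.71 ± 0.086 to 3.99 ± 0.170 CPM (mean ± SD, n = 3), and both passed when adjusted over the list alone. That list had a median of 0.28 (0.56 without control replicate 1 and 0.46 without control replicate 3) and camera adjusted p = 0.00449, but adjusted p = 0.117 with an estimated correlation. Of 11 chemokines and their receptors 0 passed the edgeR test over all genes, with 5 higher and 1 lower at an unadjusted p under 0.05 and 2 higher in DESeq2. When adjusted over the list alone, 5 were higher and 1 lower. The chemokine median was 0.21 (0.13 and 0.09 without labelled replicates 2 and 3) and camera adjusted p = 0.00817, against adjusted p = 0.121 with an estimated correlation. Ccl5, Ccrl2 and Cxcl10, picked after their values were seen, had the largest fitted log2 values, 2.38 (adjusted p = 0.0696), 2.11 (0.282) and 1.49 (0.22). Cx3cr1, the most abundant of the list, had 461.0 ± 23.2 CPM in control and 490.9 ± 9.40 CPM in the labelled group (mean ± SD, n = 3, edgeR adjusted p = 0.937). Without control replicate 1 the pathway list held 7 genes that rose, the cytokine list 3, and the chemokine list 3 that rose (Ccl4, Ccl5 and Cxcl10) and 1 that fell (Ccl9). Without any other single library 0 passed in these lists: Tlr3, Tnf and Acod1 lost their calls (adjusted p up to 0.236, 0.308 and 0.223). The chemokine list lost its call without control replicate 1 or 2 and without any labelled replicate (camera adjusted p 0.0796 to 0.185).

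**Figure D3:**
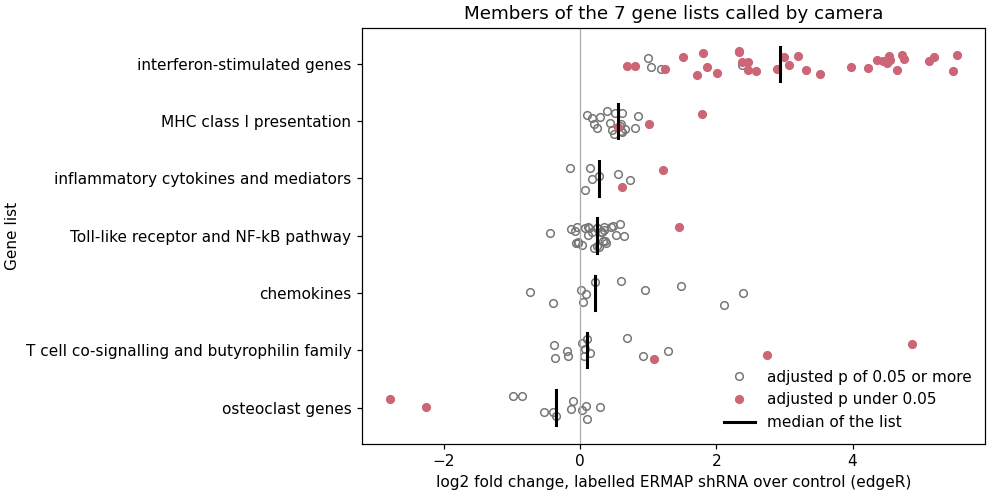
Log2 fold changes of the tested members of the 7 called lists, libraries labelled ERMAP shRNA over control, with filled points for genes with an adjusted p under 0.05 and a bar at each list's median. Mx1 is drawn at its lower bound, and the interferon list has its median at 2.94 while the other medians lie between -0.36 and 0.56.

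Of the 19 lists that camera did not call, 15 had no called member. In those 15 lists, edgeR called 0 of 331 tested genes, with 18 higher and 12 lower at an unadjusted p under 0.05 and 2 higher and 1 lower in DESeq2. Leaving out control replicate 1 gave 14 called higher and 9 lower, among them 4 higher of cholesterol synthesis, and without any other single library 0 were called. With GC offsets, 10 were called higher and 5 lower. The 15 lists are inflammasome and pyroptosis, MHC class II presentation, lysosome, macrophage identity, DNA replication, mitosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, lipid handling, unfolded protein response, oxidative stress, p53 targets, hypoxia, and heme and iron handling. Their camera adjusted p ranged from 0.0994 to 0.933. In the other 4, Fcgr1, a high-affinity IgG receptor, rose from 28.6 ± 2.34 to 89.0 ± 1.89 CPM and Axl, a receptor for dying cells, from 28.8 ± 4.69 to 64.0 ± 1.53 CPM. Egr1 rose from 3.40 ± 0.629 to 10.1 ± 0.991 CPM and Plau, urokinase, from 71.1 ± 7.11 to 106.4 ± 4.81 CPM (mean ± SD, n = 3), and Tgm2 fell within alternative activation. Alternative activation, lipid handling and p53 targets had positive medians and negative means and tests, oxidative phosphorylation a negative test with a positive median and mean, and the lysosome list a positive mean with a negative median and test. Plau lost its call without any library other than control replicate 1 (adjusted p up to 0.33), and Egr1 without labelled replicate 1 or 2 (up to 0.0532).

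Markers of other cell types stayed low. Of the 5 that passed the filter, edgeR and DESeq2 each called 0, with 2 higher at an unadjusted p under 0.05. B cell markers summed to 42.2 ± 5.60 CPM in control and 60.2 ± 6.62 CPM in the labelled group (mean ± SD, n = 3), nearly all of it Blnk, which had 42.0 and 59.9 CPM. T cell, neutrophil, dendritic cell, mast cell, fibroblast, epithelial and erythroid markers each summed to at most 3.37 CPM in either group.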

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

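The fits with library weights and with GC offsets were chosen after the results were seen, and the other alternatives before. Against 126 genes higher, DESeq2 gave 187, no filter on low counts 158, and limma-trend on log2(FPKM + 1) with no filter 81. An adjusted p under 0.01 gave 82, glmTreat against 1.5-fold 80, library weights 487 and GC offsets 268. Leaving out 1 library gave 73 to 342. Against 17 lower, DESeq2 gave 58, no filter on low counts 32, log2(FPKM + 0.1) 9, log2(FPKM + 1) with no filter 5, an adjusted p under 0.01 3, a log2 fold change of at least 1 9, glmTreat 4, library weights 430 and GC offsets 143, and leaving out 1 library gave 3 to 280. Of the left-out libraries, control replicate 1 gave 342 and 280, and labelled replicate 3 gave 73 and 3. The cause was not tested, except that stricter thresholds call fewer genes by construction and that control replicate 1 has a weight of 0.0903, the lowest of the 6. With GC offsets, 125 of the 126 genes and all 17 were still called. The common dispersion was 0.0233, 0.00939 with GC offsets and 0.0045 without control replicate 1. Ermap stayed above 0 in each alternative that gave it a value. Values ran from 0.11 on log2(FPKM + 1) with no filter to 1.66 with library weights, where it was called higher (adjusted p = 0.0382, over its alternatives up to 1). The added 1 exceeds the mean FPKM of Ermap (0.109 and 0.193), which shrinks the 0.11. The 1.66 leaned on control replicate 3, with 3 Ermap counts and a weight of 3.26. These values are not comparable fold changes, and other causes of the range were not tested. The filters on mean FPKM and mean CPM left Ermap out, so those gave no value. Of 30 named genes with a call, 15 kept it in every other fit that tested them and 0 changed direction. Against 7 lists, fry gave 11, the same 7 included, and the other alternatives 5 to 9. The cholesterol synthesis list was called higher without control replicate 1 (camera adjusted p = 0.00598), with GC offsets (0.0399) and by fry (0.00897). Mitosis was called lower without control replicate 3 (0.0436) or labelled replicate 2 (0.0438), alternative activation lower at a mean CPM of at least 1 (0.0404) or without labelled replicate 1 (0.0477), and immediate early genes higher without control replicate 3 (0.0143). Fry also called phagocytic receptors (0.0155) and DNA replication (0.0196) higher and matrix and adhesion lower (0.0322). Other scaling moved the median of all genes from -0.007 to at most -0.016.

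The replicate block gave 81 genes higher and 3 lower, each among those called without it, and the same 7 lists. Deviations of libraries of the same number had correlations of -0.286, -0.529 and 0.406, and not every library correlated best with its own number. The deviations were taken from group means that include control replicate 1, which shapes those of the other controls. The check therefore cannot decide whether the numbers pair the libraries.

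Depth limits the low genes: Ermap rests on 27 counts in the control group and 45 in the labelled group.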

Other observations

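The splits of the libraries by list, the Reactome test, the GC and length tests, the Ermap bound, the tests for lentivirus and for the interferon response, and the count of genes in other splits were chosen after the results were seen. The tests without control replicate 1 and the count of lists in other splits were set before.

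Interferon genes themselves were barely counted. Ifnb1 had 0, 0 and 0 counts in control and 2, 0 and 5 in the libraries labelled ERMAP shRNA, Ifnk had 0, 0 and 0 against 1, 1 and 0, and 18 other interferon genes had 0 counts in all 6 libraries, so no level could be compared at this depth. Ifnar1 and Ifnar2, the receptor subunits for type I interferon, had log2 fold changes of 0.00 and 0.07 (edgeR adjusted p = 0.998 and 0.949). Nos2, the inducible nitric oxide synthase, had 0 counts in all controls and 9, 11 and 8 in the labelled group. The guanylate-binding genes Gbp2 (0, 0 and 1 against 6, 7 and 8 counts) and Gbp5 (0, 0 and 0 against 4, 2 and 4) fell below the filter. So did Ciita (4, 1 and 0 against 0, 1 and 3) and Cxcl9 (0 counts in all 6 libraries), which showed no such rise. Irf1 had a log2 fold change of 0.41 (edgeR adjusted p = 0.53). All of these were picked after their values were seen.

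Outside the fixed lists, Siglec1, a sialic acid receptor of macrophages, rose from 1.81 ± 0.320 to 14.0 ± 0.667 CPM, and Sdc3, a syndecan, from 18.0 ± 4.02 to 126.6 ± 1.82 CPM (mean ± SD, n = 3). Fosl2, a subunit of AP-1, fell from 171.2 ± 19.7 to 94.3 ± 6.65 CPM and Alox5, the 5-lipoxygenase, from 258.7 ± 7.83 to 183.3 ± 6.03 CPM (edgeR adjusted p of these 4 from 0.000104 to 0.0341). All 4 were picked after their values were seen. Fosl2 and Alox5 lost their calls without control replicate 3, without any 1 of the labelled replicates, and with the replicate block. In the replicate block only Tgm2, Acp5 and Aqp1 were called lower. Of 768 Reactome sets, camera called 28 higher and 0 lower, and 3 higher with an estimated correlation: interferon gamma signalling, interferon signalling and cytokine signalling, each with adjusted p = 0.0248. Without the genes of the fixed interferon list, 16 sets were called at the preset correlation. Sets can share genes, so their calls are not independent. The interferon alpha beta set, with 12 tested genes, was among the 28 called by camera at the preset correlation (adjusted p = 3.14e-15). With an estimated correlation its camera adjusted p was 0.124. The set names thus do not tell types of interferon apart.

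Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes higher, 1 of the 10 gave as many (126, the real one), and for genes lower 1 (17, the real one), with 0 the highest of the others in edgeR. The other splits gave 36 to 514 genes in 1 direction at an unadjusted p under 0.05. For gene lists, 2 of the 10 gave 7 called, the real one and the split that puts control replicates 1 and 3 with labelled replicate 2. Each other split mixes the groups unevenly, so part of the real difference stays between its sides and part widens the spread within them. The other splits are therefore no measure of what chance alone gives. The preset correlation called the interferon list in 9 of the 9 other splits and the MHC class I list in 6. It also called lists that the real split did not: immediate early genes in 7, oxidative phosphorylation in 4, glycolysis in 3 and mitosis in 2. The Toll-like receptor, inflammasome and unfolded protein response lists were called in 1 each, and the other 17 in 0. With an estimated correlation 0 lists were called in any other split and 5 in the real one.

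The rise of interferon-stimulated genes was weighed first. A fall of Ermap mRNA by 1 or more on the log2 scale is argued against as its cause by the interval of the Ermap fold change, whose lower bound is -0.383, while a change in Ermap protein was not measured. Control replicate 1 alone is argued against, since 34 of the 34 rising list members stayed called without it. Lentiviral transduction or any shRNA, whatever its target, may account for the rise and cannot be told apart from an effect of this shRNA, since 0 control libraries have an shRNA in their treatment tags. The protocol text names the lentivirus for all 6 samples, so whether the controls were transduced stays open, as does an effect through ERMAP, which was not tested.

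The position of control replicate 1 was weighed second. A loss of short transcripts as its whole cause is argued against, because the deviation followed GC content at a given gene length (partial Spearman rho = -0.798). GC content bias is a candidate explanation: rho with GC content was -0.817, against at most 0.538 in size for the other libraries. The references for those libraries were changed to leave out control replicate 1 once a first run had shown that it shaped their values. Its share of mitochondrial counts was not explained, and no biological explanation was tested.

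The lower osteoclast genes were weighed last. Control replicate 1 alone is argued against, since without it the list median was -0.237 (camera adjusted p = 8.81e-07). The interferon response may lower these genes, and this cannot be told apart from other effects of the label, since 0 control libraries reached the interferon list level of the labelled group. With GC offsets, 6 of 13 list members fell, among them Nfatc1, Dcstamp and Mitf.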
